A study of Caenorhabditis elegans with 2 samples.

How the data were processed

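LIN-13 ChIP-seq was represented by 2 biological replicates of mixed-stage embryos of strain OP51, which carries the transgene wgIs51 in an unc-119 mutant background. Both were in 1 group, with a fragment size range of 150 to 350 in the labels. A control experiment named in the labels was not analysed here. Replicate numbers were taken from the labels. No second group was present, so no comparison between conditions was made and no pairing of replicates applied.

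The deposited files were region lists in narrowPeak format for the builds ce11 and ce10, with 4 lists per build. Per the file headers beside the lists, each replicate's list came from the alignments of that replicate and a control, the pooled list from both replicates together, and the final list from these 3 lists by IDR. The aligner, the peak caller, the IDR threshold and their versions are not given in the sources used here. The replicate and pooled lists each held 30000 regions, a ceiling that lets them reach into background, and the IDR list was the first 1534 ranks of the pooled ce11 list (1608 in ce10). Column 7 of the deposited lists is the peak caller's signal per region, on a scale that differs between lists, so it was used only to rank regions within a list and to describe single peaks. Column 9 of the deposited lists is a −log10 q value. All 1534 IDR peaks shared the ceiling of 3.51 in it, so it could not rank them and no result uses it. Region widths had medians of 220 bp in replicate 1, 316 bp in replicate 2 and 284 bp in the pooled list. The lists hold no read counts, so depth per sample is unknown. The intervals given are exact binomial intervals (95%) over peaks or genes and do not include error in the reads.

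The reference genome and annotation were of WBcel235, which is ce11, and the ce11 lists were used for every value unless ce10 is named. All coordinates are ce11, counted from 1. Positions were not converted between builds. Only the 6 nuclear chromosomes were used. Summits within 100 bp of each other were to be counted once, but no pair of IDR summits was that close (the smallest spacing in the list was 199 bp). Lower-ranked regions were those of the pooled list with a summit over 1000 bp from every IDR summit (27480 regions). They pass the same mapping and control correction as the IDR peaks.

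Placement tests shifted all summits of a chromosome together by a random distance around that chromosome, 100000 times, which keeps their spacing. The promoter share used 500 bp upstream to 200 bp downstream of every annotated protein-coding TSS. Masked sequence was the lower-case share of the 200 bp around the summit, and lower case covers 35.7% of the 6 chromosomes. This mask does not tell kinds of repeat apart, and how much of it is repeat elements was not tested. Gene lists and gene biotypes used 1000 bp upstream to 200 bp downstream of any TSS of the gene, with Fisher's exact test against all other protein-coding genes for lists and against protein-coding genes for biotypes, and Benjamini-Hochberg adjustment over 16 lists, 10 biotypes or 6 motifs. Genes inside operons have no promoter of their own. Gene symbols were matched to the annotation and to synonyms in the reference gene table. Of the 17 heat shock symbols, 3 were unmatched (daf-21, hsp-16.11 and hsp-16.49). Symbols that the annotation gives to several near-identical genes counted for each of those genes, so 16 heat shock genes and 72 histone genes were tested. Peaks and genes are not independent replicates, so these tests describe the peak lists of this experiment. The correlation of signal between replicates is given with no p-value for the same reason.

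The main tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule named the genes nearest to the 25 strongest IDR summits, up to 4 members of each list with the highest-signal peak in the window, and lin-13 and unc-119 whatever their values. The matching of symbols to genes was corrected after values had been seen, which added members to the histone, ribosomal and heat shock lists. The predictions of 2 tests on the lin-13 locus were also rewritten after their values had been seen. The nearest annotated TSS was that of a noncoding RNA for 3 of the 25 summits. The nearest protein-coding gene is given for all of them, a choice made after the data were examined, and the 3 noncoding RNAs are named beside it.

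The alternatives were other promoter windows, summit distances, numbers of top regions, mask shares and motif windows, random placement of single summits, GC-matched background regions, ce10 lists, stricter peak sets and the top 1534 regions of each replicate alone. The chromosome by chromosome tests, the summit locations, the tRNA share in lower-ranked regions, the gene families by symbol and the regions found in a single replicate were added after the data were seen. Tests of explanations for peaks at ribosomal protein and cell cycle genes were not among the tests fixed beforehand. Nor were those for the lack of regions around lin-13.

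The functions were tested on simulated data. For the promoter share with 1534 summits placed uniformly, 2 of 100 simulations had p under 0.05, and with summits planted at promoters to make a share of 41.5% the mean share recovered over 20 simulations was 41.6%. For the gene lists over 19973 genes, 3 lists were planted at a share of 50%, with other genes at 8%. All planted lists were called (100%) and 0.308% of the other lists were. Lower planted shares were not simulated, so it is unknown how often lists with a smaller excess would be called. This simulation drew each gene independently, so it does not cover peaks shared between neighbouring genes. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.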

Results

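Binding of LIN-13 was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mixed-stage embryos of the nematode Caenorhabditis elegans. LIN-13 is a zinc finger protein of the synthetic multivulva class B (synMuv B) group, whose members restrain vulval fate genes, and it is known to act with the HP1 homolog HPL-2. The worms were of strain OP51, which carries an integrated transgene expressing LIN-13 fused to enhanced green fluorescent protein, and whole animals of mixed sex were used. The labels describe the target as the tagged protein but give lin-13 in the antibody field, so it is open whether the antibody recognised the tag or LIN-13 itself, and whether untagged LIN-13 was also recovered. The 2 samples, which the labels call biological replicates, formed 1 group, so agreement between replicates was the only comparison between samples. Each replicate had its own list of 30000 ranked regions, a pooled list of 30000 regions came from both replicates together, and the authors' final set held 1534 peaks. The final set was derived with the irreproducible discovery rate (IDR), a method that weighs how well ranks recur between replicates. It equals the first 1534 ranks of the pooled list, so a single member need not recur in both replicates. The lists give positions and signal values but no read counts, so the sequencing depth is unknown and no interval for counting error in the reads could be given.

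The strongest LIN-13 peaks lay upstream of protein-coding genes of several kinds, of which ribosomal protein genes were the most frequent of the lists fixed beforehand. The first was on chromosome III at 3867455 to 3867695 (ce11), in intergenic sequence with its summit 279 bp upstream of rpl-3 (WBGene00004414), a large ribosomal subunit protein gene. Its signal was 487.5, and it ranked 1 in both replicates. The next was on chromosome IV at 654809 to 655034, 352 bp upstream of rpl-15 (WBGene00004427) in intergenic sequence, with a signal of 355 and ranks of 2 and 8 in replicates 1 and 2. All 25 strongest peaks had their summit upstream of the nearest protein-coding transcription start site (TSS), at 3 to 509 bp, and 8 of the 25 had a ribosomal protein gene within the window of 1000 bp upstream to 200 bp downstream of a TSS. By nearest coding TSS these 25 belonged to rpl-3, rpl-15, tasp-1, Y17G9B.5, his-68, rps-1, hsr-9, rpl-35, cdc-48.1, iff-2, hsp-1, trap-3, ddp-1, K12H4.5, cox-5A, serp-1.1, wip-1, eelo-2, ska-3, Y22D7AL.10, rps-28, cox-5B, tos-1, his-32 and Y71H2AM.20. For 3 of them an annotated noncoding RNA started closer to the summit: F56F3.11 beside rps-1, F26D10.23 beside hsp-1 and Y38F2AR.16 beside trap-3. Several of these peaks also lay in the window of another gene, as with Y17G9B.5 and rpl-20, and with ska-3 and rps-12. Of the 25 peaks, 22 were among the first 100 regions of both replicates. The exceptions were at his-68 (ranks 522 and 2), hsp-1 (292 and 5) and his-32 (614 and 9), which all stood much higher in replicate 2.

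The replicates shared their strongest regions far more often than chance placement gave. Of the 1534 strongest regions of replicate 1, 785 (51.2%) had a summit within 100 bp of one of the 1534 strongest of replicate 2, against 0.329% when the summits were shifted around each chromosome (one-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). The share was 51.8% for the top 500 and 32.4% for the top 5000. Of the 1534 IDR peaks, 1436 had a region in the list of replicate 1, 1467 in that of replicate 2 and 1373 in both. Over those 1373 peaks the Spearman correlation of the signal between replicates was 0.284, a value across peaks of the same libraries, which are not independent replicates. These peaks were selected on the pooled signal, which narrows its range and can lower the correlation. A subset of 790 IDR peaks (51.5%) was among the top 1534 regions of both replicates, and 67 were in the top of neither.

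**Figure D1:**
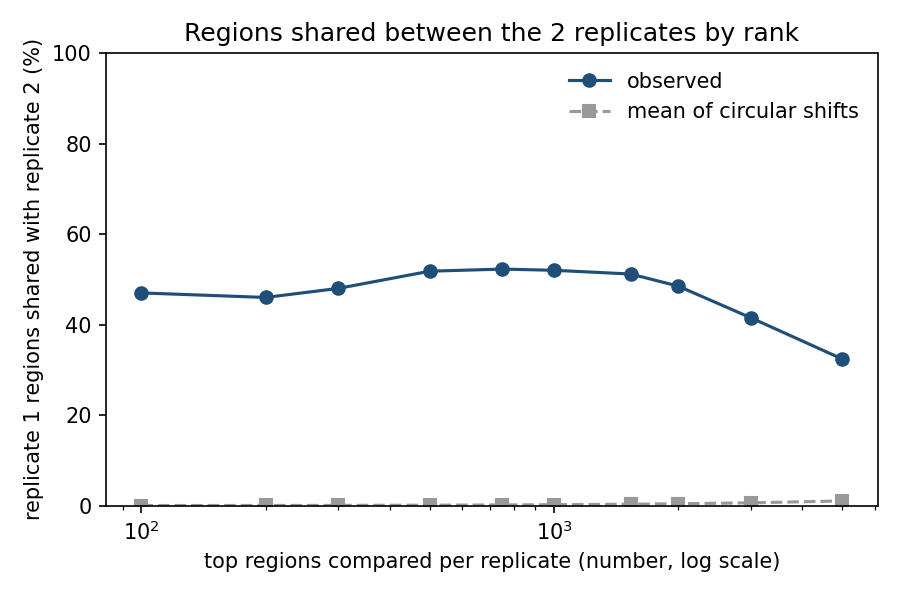
Percent of the top regions of replicate 1 with a summit within 100 bp of a top region of replicate 2 (vertical axis), for 100 to 5000 top regions per replicate (horizontal axis, log scale), with the mean of circular shifts as squares. The observed share stays between 46.0% and 52.3% up to 1534 regions and is 32.4% at 5000, while the shifted share is at most 1.05%.

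LIN-13 peaks were concentrated at promoters and nearly absent from coding exons. Of the 1534 summits, 1013 (66.0%, exact 95% binomial interval 63.6% to 68.4%) lay between 500 bp upstream and 200 bp downstream of a protein-coding TSS, 4.11 times the 16.07% given by circular shifts (two-sided permutation test, p = 1e-05, the smallest possible). The share was 19.6% in 27480 lower-ranked regions of the pooled list that lay over 1000 bp from every IDR summit (odds ratio 7.96, Fisher's exact test, p = 8.22e-318). The median distance to the nearest coding TSS was 258 bp for IDR peaks and 1244 bp for lower-ranked regions, and 83.9% of IDR summits were upstream of that TSS against 44.3% of lower-ranked ones. By annotation, 1077 summits (70.2%) were intergenic, 212 (13.8%) intronic, 169 (11.02%) in exons of noncoding genes, 54 (3.52%) in 5′ untranslated regions and 12 (0.782%) in 3′ untranslated regions. Coding exons held 10 summits (0.652%), where circular shifts gave 24.7% and lower-ranked regions 26.1%. In exons of noncoding genes shifts gave 3.10% and lower-ranked regions 4.02%, both below the share of IDR summits. Shifts gave 32.6% for intergenic sequence, 34.8% for introns, 1.42% for 5′ and 3.41% for 3′ untranslated regions. Many annotated worm TSSs are trans-splice sites, which lie downstream of the site where transcription begins.

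**Figure D2:**
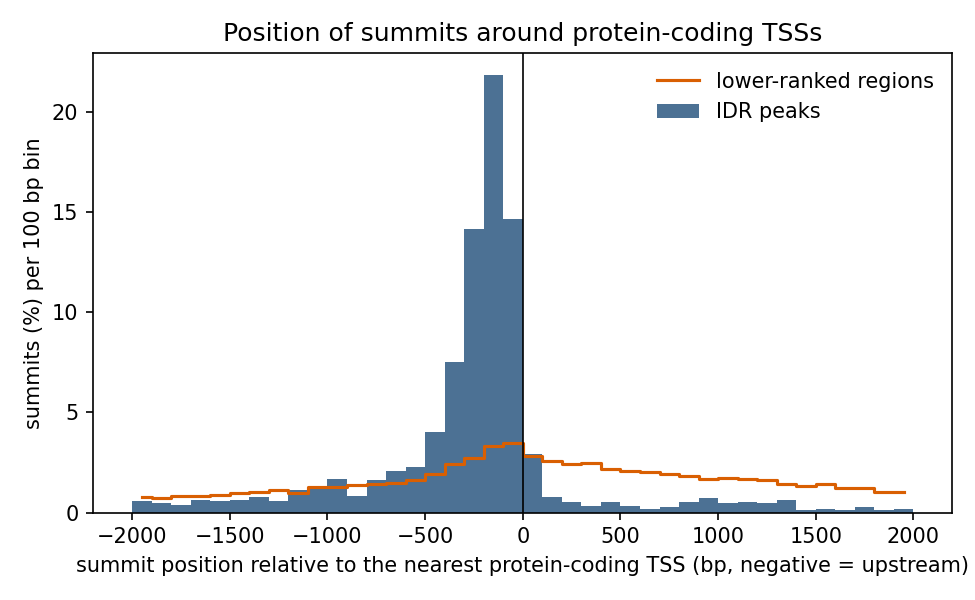
Position of the summit relative to the nearest protein-coding TSS in bp (horizontal axis, negative is upstream) against the percent of summits in each 100 bp bin (vertical axis), for the 1534 IDR peaks (bars) and 27480 lower-ranked regions (line). The highest bin of the IDR peaks, 100 to 200 bp upstream, holds 21.8% of them against 3.34% of the lower-ranked regions.

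Genes for the translation machinery, cell division and the synMuv B group itself carried LIN-13 peaks more often than other genes, and few or none of the listed markers of differentiated tissues did, a lower share that passed no test. In all, 1626 of 19973 protein-coding genes (8.14%) had an IDR summit from 1000 bp upstream to 200 bp downstream of a TSS, and 7 of 16 gene lists differed from the remaining genes, all with higher shares (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over the 16 lists). Of 78 cytosolic ribosomal protein genes 66 had a peak (84.6%, odds ratio 64.6, exact adjusted p = 9.86e-59), led by rpl-3, rpl-15, rpl-20 (signal 299.5) and rps-1 (signal 280.3). Of 46 cell cycle and DNA replication genes 22 had one (47.8%, odds ratio 10.5, exact adjusted p = 8.82e-12). Among them were pcn-1, the replication clamp, with its summit 265 bp upstream and a signal of 148.7, the kinetochore gene knl-1 with a signal of 80.96, the spindle checkpoint gene mdf-2 with a signal of 79.5, and the centrosome gene spd-5, whose summit was 207 bp downstream of the nearest of its TSSs, in an intron, with a signal of 70.8. Of 16 heat shock genes 8 had a peak (50%, exact adjusted p = 5.39e-05), with hsp-1, hsp-60, hsp-3 and hsp-90 the highest at signals of 214.2, 191.8, 155.4 and 154.9.

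Of 21 genes for synMuv B, DREAM and HP1 complex members, 10 had a LIN-13 peak (47.6%, odds ratio 10.3, exact adjusted p = 1.01e-05). The DREAM complex represses cell cycle genes, and its members lin-54, lin-53, lin-9 and efl-1 had the highest signals of the list. The lin-54 (WBGene00003037) peak was intergenic on chromosome IV at 13240611 to 13240747, 371 bp upstream of the TSS, with a signal of 135.8 and ranks of 67 and 59 in the replicates. The same peak lay in the window of the ribosomal protein gene rpl-12, so it counts for both lists. The lin-53, lin-9 and efl-1 peaks had signals of 96.9, 96.1 and 93.3, at 219, 166 and 167 bp upstream. Of 34 small RNA pathway genes 10 had a peak (29.4%, exact adjusted p = 0.000848). The highest was at alg-5 (signal 286.2), where the summit was 838 bp upstream and lay closer to the histone genes his-67 and his-68. It was followed by mut-15 (signal 116.5), nrde-2 (80.98) and wago-4 (61.5). Of 18 chromatin silencing and nuclear envelope genes 5 had a peak (27.8%, exact adjusted p = 0.0284), with npp-14 (signal 135.0), mrg-1 (92.7), lem-2 (58.7) and mes-2 (54.8) the highest. Histone genes had 15 of 72 (20.8%, exact adjusted p = 0.00156). The highest were his-67 and his-68 under a single peak, and his-31 and his-32 under another with a signal of 171.2. Histone genes are near-identical copies in clusters, so reads can be shared between them and the count per gene is uncertain.

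The other 9 lists did not pass the test. Dosage compensation and sex determination genes had 4 of 18 (22.2%, exact adjusted p = 0.107), at dpy-27, dpy-30, mix-1 and fem-1, with signals of 57.1, 50.1, 47.1 and 35.4. Meiosis genes had 5 of 29 (17.2%, exact adjusted p = 0.146), the highest at brc-1, him-17, spo-11 and coh-3, with signals of 49.4, 47.8, 44.3 and 43.2. The spo-11 peak had no region in the list of replicate 2. P granule and germline RNA genes had 2 of 28, mex-1 (signal 133.6) and cgh-1 (112.3), whose TSSs were 927 and 779 bp from the summits. Vulval induction signalling genes had 2 of 21, lin-7 and sur-2, and Hox and axial patterning genes had 1 of 10, ceh-20. The vulval list had 4 of 21 without replicate 2 (exact adjusted p = 0.127) and 2 of 21 without replicate 1. Neuron markers had 1 of 26, ric-19, with a signal of 38.3. The lists of 20 intestine, 20 muscle and 22 hypodermis and cuticle markers had none, which did not pass the test (exact adjusted p = 0.536, 0.536 and 0.405). None is the lowest count possible, so lists of this size could not have passed this test as lower. A peak can serve more than 1 gene: 467 of the 1125 peaks in these windows lay in the windows of at least 2 genes. When each peak was instead given to the gene of its nearest coding TSS alone, at any distance, 4 lists passed and the ribosomal share was 48.7%. The histone, heat shock, small RNA and chromatin silencing lists no longer passed (exact adjusted p = 0.209, 0.209, 0.209 and 0.118), while the dosage compensation list did (exact adjusted p = 0.0305), as it did without replicate 2 (exact adjusted p = 0.0222). This rule drops both the sharing of peaks and the window, whose effects were not separated. Over the 8 alternatives run on each list, the exact adjusted p ranged from 6.32e-07 to 0.209 for histone, 1.03e-06 to 0.209 for heat shock, 0.00327 to 0.209 for small RNA, 0.00336 to 0.345 for chromatin silencing and 0.0222 to 0.663 for dosage compensation genes.

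**Figure D3:**
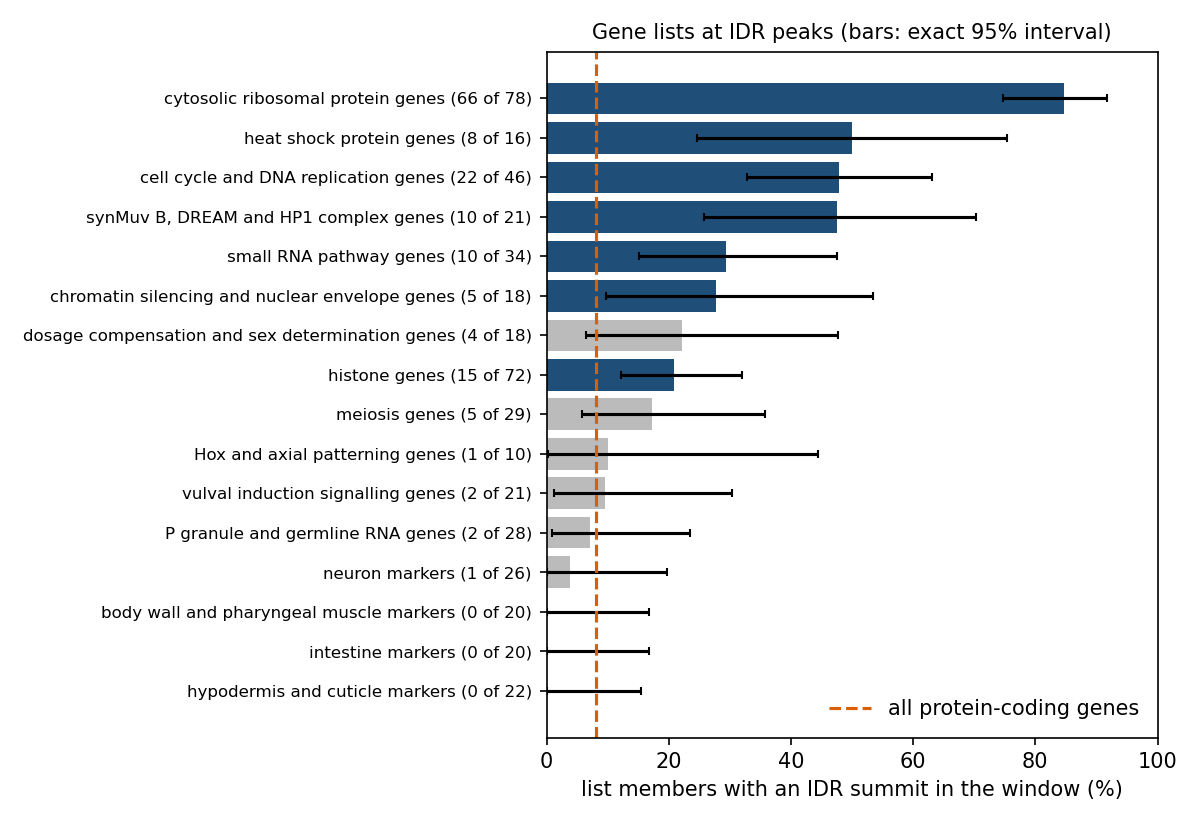
Percent of the members of each of 16 gene lists with an IDR summit from 1000 bp upstream to 200 bp downstream of a TSS (horizontal axis), with exact 95% binomial intervals as error bars and the counts in the row names; dark bars passed the adjusted test and the dashed line is the 8.14% of all protein-coding genes. The shares run from 84.6% for ribosomal protein genes to 0 for intestine, muscle and hypodermis markers.

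Transfer RNA genes and small nucleolar RNA genes were also found at LIN-13 peaks, and piRNA genes and pseudogenes rarely were. Of the 1534 summits, 84 (5.48%, exact 95% interval 4.39% to 6.73%) were within 200 bp of a tRNA gene, 19.7 times the 0.278% of circular shifts (one-sided permutation test, p = 1e-05, the smallest possible), and the share in lower-ranked regions was 0.906%. The share differed between replicates and was 6.58% in the top 1534 regions of replicate 2 alone and 2.35% in those of replicate 1 alone. Transfer RNA genes are often recovered in worm ChIP-seq whatever the tag, the reason this test was planned. No untagged strain was used, so whether these peaks are particular to LIN-13 was not tested. Within 1000 bp upstream to 200 bp downstream of their TSS, 28.3% of 346 snoRNA genes and 16.99% of 612 tRNA genes had a peak, against 8.14% of protein-coding genes (Fisher's exact test adjusted over 10 biotypes, exact adjusted p = 4.63e-27 and 7.91e-12). With replicate 1 alone the share of tRNA genes with a peak was 7.52% and did not pass the test (exact adjusted p = 0.761), nor did it in the 767 strongest peaks (5.72%, exact adjusted p = 0.282) or the 790 in the top of both replicates (5.07%, exact adjusted p = 0.860). Compared with protein-coding genes, peaks were less frequent at piRNA genes (75 of 15363, 0.488%) and pseudogenes (18 of 2128, 0.846%). They were also less frequent at genes annotated as ncRNA (361 of 7764, 4.65%) and antisense RNA genes (0 of 100). In that order the exact adjusted p was 5.19e-309, 6.59e-50, 1.66e-25 and 0.000568. These tests count genes as independent, though 1 peak can lie in the windows of several genes. They do not compare with chance placement, which gave fewer summits in exons of noncoding genes than were seen. The 24 of 261 miRNA genes, 15 of 129 snRNA genes, 10 of 194 lincRNA genes and 0 of 20 rRNA genes with a peak did not pass the test (exact adjusted p = 0.496, 0.183, 0.183 and 0.447). The snRNA share passed as higher with 500 bp upstream and in the 767 strongest peaks (exact adjusted p = 0.0482 and 0.0303). The lincRNA share passed as lower without replicate 2 (3.09%) and in the 790 peaks in the top of both replicates (1.55%; exact adjusted p = 0.0170 and 0.0454).

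LIN-13 peaks lay in mostly soft-masked sequence less often than summits shifted along the chromosomes. The LIN-13 partner HPL-2 binds chromatin with methylated lysine 9 of histone H3, which covers repeats. Bases that are soft-masked in the reference were used here as a rough measure of repeats. Methylation was not measured, and how much of the mask is repeat elements was not tested. The central 200 bp was over 50% masked in 217 summits (14.1%, exact 95% interval 12.4% to 15.99%), where circular shifts gave 27.7% (two-sided permutation test, p = 1e-05, the smallest possible). The share in lower-ranked regions was 21.2% (odds ratio 0.614, Fisher's exact test, p = 7.77e-12). With any masked base counted, the shares were 84.7% and 85.0% and the test was not passed (exact p = 0.769). Without replicate 2 the difference from lower-ranked regions was also lost. The shares were 10.4% in both kinds of region of replicate 1 (exact p = 0.966). Shifts of its top regions gave 27.4%, so the shortfall against shifts was not particular to them. Neither GC content nor promoter position was matched in these comparisons. Among the top regions found in a single replicate, 6.81% of those of replicate 1 and 21.2% of those of replicate 2 were over 50% masked.

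Under the summits, E2F-like sites and GAGA repeats were more frequent than in lower-ranked regions. The E2F-like sequence TTSSCGC (S is C or G) was within 100 bp of 20.3% of IDR summits against 10.8% of lower-ranked ones (odds ratio 2.098, Fisher's exact test adjusted over 6 motifs, adjusted p = 6.83e-25). GAGAGAGA was found at 8.67% against 3.01% (odds ratio 3.06, exact adjusted p = 3.82e-24) and CCRCCC (R is A or G), a zinc finger type site, at 17.8% against 11.6% (odds ratio 1.65, exact adjusted p = 9.12e-12). The sequence HGATAR (H is A, C or T), bound by GATA factors, was less frequent (32.7% against 37.0%, exact adjusted p = 0.000657), as were TTTTTTTTTT (2.48% against 5.13%, exact adjusted p = 7.49e-07) and the cell cycle homology region TTYGAA (Y is C or T; 42.96% against 46.2%, exact adjusted p = 0.0144). The windows had a median GC content of 44.8% at IDR summits and 40.3% in lower-ranked regions. The medians were 50.5% and 41.6% within 50 bp, and 37.7% and 38.5% within 250 bp, so the excess lay close to the summit. Against lower-ranked regions matched in GC the E2F-like and GAGA differences stayed (11.3% and 3.85% in the matched regions), those of HGATAR, TTTTTTTTTT and CCRCCC were lost (exact adjusted p = 0.908, 0.881 and 0.165), and TTYGAA turned to more frequent at IDR summits (36.8% in the matched regions, odds ratio 1.29, exact adjusted p = 0.00121). The lower share of TTYGAA was also lost within 250 bp, in the 767 strongest peaks and in the 790 in the top of both replicates (exact adjusted p = 0.363, 0.255 and 0.856). That of HGATAR was lost in the latter (exact adjusted p = 0.0678) and turned to higher within 250 bp (odds ratio 1.26). The GAGAGAGA share was 5.57% in those 790 peaks (odds ratio 1.90, exact adjusted p = 0.00043). The 2 kinds of region were not matched on promoter position, where 66.0% of IDR summits and 19.6% of lower-ranked ones lay. Whether these motif differences belong to promoters in general was not tested.

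Peaks were densest on chromosomes III and I and sparsest on V, and the share on the X chromosome was close to its share of length but above its share of genes. Chromosome III had 22.2 IDR summits per Mb, I had 19.8, II 16.43, X 15.7, IV 12.1 and V 9.08. The lower-ranked regions had the same order, with 358.5 per Mb on III, 325.6 on I, 303.9 on II, 241.4 on X, 229.7 on IV and 224.3 on V. The X held 278 summits (18.1%, exact 95% interval 16.22% to 20.1%) where its length gives 17.7% (exact binomial test, two-sided, p = 0.639). The replicates differed in this: the X share was 20.1% in the top regions of replicate 1 (exact p = 0.0145) and 15.3% in those of replicate 2 (exact p = 0.0159), on opposite sides of the length share. In tests added after the data were seen, the shares of III and I were above and those of IV and V below their share of length (exact binomial test adjusted over 6 chromosomes, exact adjusted p = 6.27e-11, 6.55e-06, 0.000161 and 2.98e-17). Per 1000 protein-coding genes, III had 115.9 summits, I 103.5, X 101.8, II 72.8, IV 64.3 and V 38.0. Against shares of protein-coding genes, X (18.1% of summits and 13.7% of genes), III and I were above and IV and V below (exact binomial test, exact adjusted p = 1.60e-06, 7.72e-13, 1.68e-07, 0.00507 and 8.23e-34), and II did not pass the test (0.362). On the autosomes, 588 of 1256 summits (46.8%, exact 95% interval 44.0% to 49.6%) were in the outer parts of each chromosome, which together cover 50% of its length (exact binomial test, p = 0.0258). The share was 42.7% in replicate 1 alone and 51.04% in replicate 2 alone. Lower-ranked regions had 61.1% there. Peaks cluster along chromosomes, and these binomial tests treat them as independent.

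**Figure D4:**
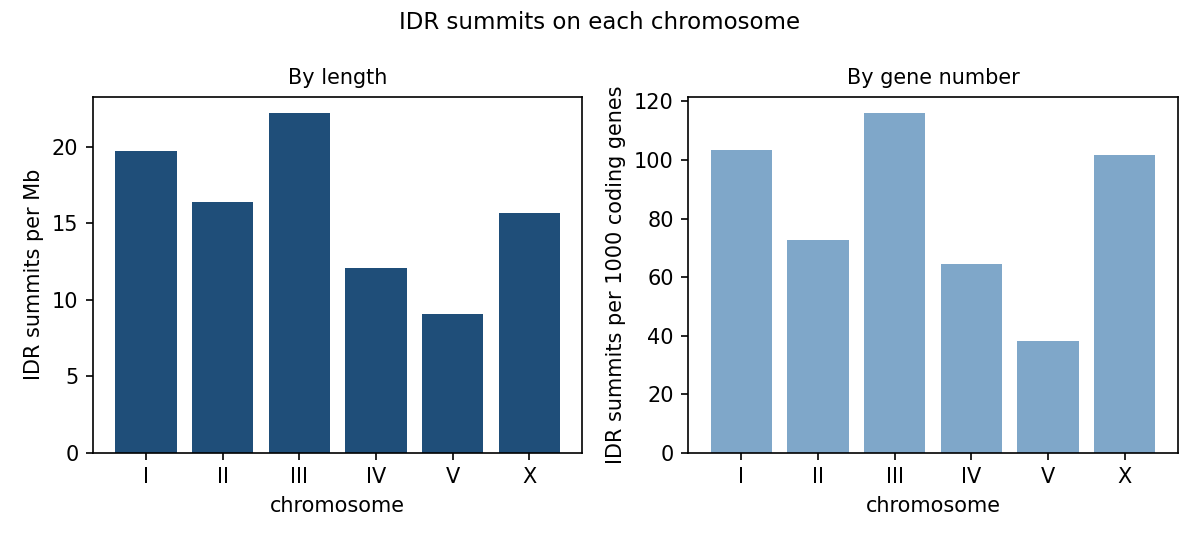
IDR summits per Mb (left) and per 1000 protein-coding genes (right) on each of the 6 nuclear chromosomes (horizontal axes), as bars from 0. Both panels have their highest bar on III (22.2 per Mb and 115.9 per 1000 genes) and their lowest on V (9.08 and 38.0).

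At the tagged gene itself, lin-13 (WBGene00003002, chromosome III, 7700338 to 7709491, minus strand), no region was listed within the gene or 1000 bp on either side in the pooled list or in either replicate. At unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935, plus strand), the gene whose mutation in this strain is used to select the transgene, 7 regions of the pooled list lay in the gene and its flanks. The best of these ranked 6562, far below the last IDR peak.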

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

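Of 87 alternatives run on the 14 main values, 74 kept their result: a test its direction and side of the threshold, a count within 1.5 times, and the correlation within its bootstrap interval of 0.237 to 0.3351. The promoter share, the share of summits within 200 bp of a tRNA gene, the masked share against circular shifts and the replicate overlap kept theirs under every alternative run. The correlation of signal between replicates lay just outside it, at 0.3353 with summits within 50 bp and 0.233 within 250 bp. The number of peaks fell to 790 among the top 1534 regions of both replicates, by construction. The number without merging, counted among those kept, could not change, since no IDR summits lay within 100 bp of each other. For masked sequence against lower-ranked regions, the odds ratio was 0.978 when any masked base counted (Fisher's exact test, p = 0.769), and 0.642 to 0.991 without 1 replicate. The X share of 18.1% passed the test against the X share of lower-ranked regions (exact p = 0.00666), was 15.9% in the peaks in the top of both replicates and was 15.3% to 20.1% without 1 replicate. The arm share was 47.5% in the 767 strongest peaks (exact p = 0.216, with fewer peaks tested) and 42.7% to 51.04% without 1 replicate. With GC-matched regions 3 of 6 motifs passed, and with the nearest TSS alone, at any distance, 4 of 16 lists. The cause was not tested for these or the others.

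Among single lists, motifs and biotypes, 16 of 220 alternatives turned the direction, mostly of lists that passed no test. HGATAR had an odds ratio of 1.26 within 250 bp, and TTYGAA 1.29 against GC-matched regions. For lists and biotypes the direction is against the comparison genes, whose share changed with the setting. Hox genes had 0% at peaks with 500 bp upstream and 10% with 2000 bp, against 6.72% and 10.3% of other genes. Among genes with any pooled region they had 14.3%, against 19.7%. P granule genes had 10.7% with 2000 bp and 20% among genes with any pooled region, against 10.3% and 19.7% of other genes. They had 7.14% in the 767 strongest peaks and in the peaks in the top of both replicates, against 4.57% and 4.82%. Without replicate 2 they had 10.7%, against 7.92%. Without replicate 1 their 7.14% stayed below the 7.26% of other genes. Vulval genes had 15.4% among genes with any pooled region, against 19.7%, and 4.76% in the peaks in the top of both replicates, against 4.82%. Meiosis genes had 0% in the 767 strongest, against 4.58%. Of miRNA genes, 6.51% had a peak with 500 bp upstream, against 6.71% of protein-coding genes. In the peaks in the top of both replicates the shares were 4.60% and 4.82%. Without replicate 2, 7.52% of tRNA genes had a peak, against 7.92% of protein-coding genes. Without replicate 1 the shares were 20.6% and 7.26%. The small RNA list had an exact adjusted p = 0.0551 with 500 bp upstream and 0.0525 among genes with any pooled region, and the chromatin silencing list 0.345 among the latter. Depth limits are unknown, since the lists hold no reads.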

Other observations

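The tests of regions in a single replicate and of gene families by symbol, and 2 tests on lin-13 (chance spacing and extra copies), whose predictions replaced earlier ones, were chosen after the results were seen. The other tests of explanations below were also not among those fixed beforehand. The earlier prediction for extra copies would have counted that explanation as met, but its bound was already passed by the stretch that had been seen, and the replacement left it open. Grouping all protein-coding genes by symbol prefix gave 175 families of at least 10 members, of which 23 had a higher and 15 a lower share at LIN-13 peaks than other genes (Fisher's exact test, Benjamini-Hochberg adjusted over the 175). Beyond ribosomal proteins, the higher ones included, by Fisher's exact test, translation initiation factors (eif, 12 of 25, adjusted p = 7.18e-06), cytochrome c oxidase subunits (cox, 9 of 15, adjusted p = 1.71e-05), secretory pathway genes (sec, 9 of 19, adjusted p = 0.000146), nuclear pore proteins (npp, 10 of 26, adjusted p = 0.000312), DnaJ chaperones (dnj, 10 of 29, adjusted p = 0.00086) and mitochondrial large ribosomal subunit proteins (mrpl, 11 of 41, adjusted p = 0.00353). By the same exact test, the lower ones were large families that include chemoreceptors (str, 0 of 193, adjusted p = 7.18e-06; srh, 2 of 220, adjusted p = 7.76e-05), C-type lectins (clec, 3 of 240, adjusted p = 0.000104), F-box proteins (fbxa, 1 of 170, adjusted p = 0.000254), nuclear hormone receptors (nhr, 8 of 269, adjusted p = 0.00637) and collagens (col, 3 of 156, adjusted p = 0.0128).

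Regions among the top 1534 of a single replicate differed in kind. Of the 749 found in replicate 1 alone, 53.7% were at promoters and 1.60% near tRNA genes, with a median GC content of 47.3% and 40.1% of the autosomal ones in the outer parts of the chromosomes. Of the 749 found in replicate 2 alone, 42.7% were at promoters and 10.3% near tRNA genes, with a median GC content of 43.3% and 57.4% in those outer parts. The odds ratios of replicate 1 over replicate 2 were 1.55 for promoters and 0.142 for tRNA genes (Fisher's exact test, p = 2.76e-05 and 2.05e-13), which compare these 2 libraries and not conditions. In the 785 regions shared by both, 75.03% were at promoters.

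Peaks at ribosomal protein genes raise the question of whether the signal is particular to them. GC content of the promoter was argued against: the ribosomal share was 9.85 times that of other coding genes matched on promoter GC (84.6% against 8.59%, Fisher's exact test, p = 1.62e-52). The median promoter GC was 36.6% for ribosomal protein genes and 34.95% for all other coding genes. Matching therefore moved the share of the others little from its 7.84%. GC content under the summits was not matched in this test. Recovery of any highly transcribed promoter, whatever the tagged protein, stays open. Of 39 abundantly transcribed genes outside the ribosome, a list written before the test from general knowledge and not from measured expression, 59.0% had a peak, below the ribosomal share (Fisher's exact test, p = 0.00504) but far above the 7.74% of other coding genes (p = 3.53e-16). A ChIP of an untagged strain or another tagged factor was not used here, the antibody's target is not settled by the labels, and no biological explanation was tested.

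No region was listed around lin-13 in any of the 3 lists. The stretch without a summit ran from 7661271 to 7728632 on chromosome III in the pooled list, 67361 bp where the median spacing is 1751 bp, the 10th longest in that list after one of 142012 bp on V and others, and its counterpart was the 21st longest in replicate 2. Chance spacing was argued against for a gene named in advance, since 0.811% of protein-coding genes lie in a stretch as long, by a bound set after that value had been seen, and stretches as long do occur at other loci. Repeat-rich sequence, as far as soft-masked bases measure it, was argued against. The masked share of the stretch, 27.6%, is at the 17.8th percentile of stretches of that length on the chromosome. Extra copies of lin-13 sequence in the transgenic strain, in the ChIP and the control alike, are a candidate explanation that stays open: the part empty in all 3 lists covers the whole gene but is 55.77 kb long, longer than the 45 kb taken, after the stretch had been seen, as about the length of a cloned insert, and neither reads over the locus nor a biological explanation was tested.

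Peaks at cell cycle and DNA replication genes may go with E2F-like sites, which DREAM complexes are known to bind. An E2F-like site was within 100 bp of 15 of the 22 peaks at listed cell cycle genes (68.2%, exact 95% interval 45.1% to 86.1%) and of 21.5% of 1103 other peaks in coding gene windows (odds ratio 7.83, Fisher's exact test, p = 4.60e-06). GC content under the peaks was argued against, because other peaks in the same GC bins had a site in 22.4% of cases, a ratio of 3.05. The median GC content was 41.3% in the cell cycle peaks and 42.8% in the others. Matching therefore moved the share of the others little from its 21.5%. Listed cell cycle genes without a peak were not searched for the site. The comparison therefore cannot tell sites that go with LIN-13 peaks from sites common to cell cycle promoters. The hypothesis was tested on the same data that gave the peaks, and no second factor was measured here, so whether LIN-13 is bound there through such a complex was not tested.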
